A study of Mus musculus with 2 samples.

How the data were processed

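RNA of 2 sublines of SV40 MES13 was measured, 1 library per group. Per the labels, cells were infected with the AI662270 lentivirus or a control lentivirus, selected with 0.5 mg/ml and kept in 0.25 mg/ml puromycin in medium with 10% serum. The labels call the material polyadenylated RNA and the design text says that mRNA was taken after removal of ribosomal RNA, so which selection was used is not settled here. Libraries were sequenced on an Illumina HiSeq instrument, per the series design text. The submitters' processing notes name CASAVA 1.4, TopHat2 and build mm10. The read counter, the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart and are named as uncertain.

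The deposited table of all genes held 54713 rows. Its count columns hold whole reads per gene with no normalization by the authors, judged from whole values with a different total in each library. The deposited FPKM columns equal the counts divided by gene length and by a single divisor of 15391166 in both libraries, so a ratio of FPKM is a ratio of raw counts. The signal columns hold counts that the authors rescaled toward a common library size, per the file headers and values, and were not used. The log2 fold changes and the p-values of 1 library against 1 library are the authors' own, per the file headers, and are quoted only as counts of genes listed. A second deposited table held the same 897 genes that had an adjusted p-value under 0.05 in the table of all genes. Of the rows, 181 were loci without an Ensembl identifier that the authors had added. Of 54532 Ensembl identifiers, 99.8% were in the GENCODE M21 annotation of the same build, and 98.3% of those matched had the same coordinates there. In that annotation AI662270 has 4 transcripts and 10 exon records, and its deposited length of 3029 bases equals the whole span.

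Libraries were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 0.967 for the control and 1.03 for the AI662270 library. CPM and log2 ratios were computed with a pseudocount of 0.5 CPM in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A gene counted as measured at a mean of at least 1 CPM over the 2 libraries. The log2 ratio understates the change of low genes, so folds are ratios of CPM without the pseudocount. The interval of a ratio is the exact Clopper-Pearson interval of the share of 2 counts at a confidence level of 95%. A gene was called higher or lower by a rule of size: a log2 ratio of at least 1 in either direction and an interval without 1. No p-value across genes was computed, since 1 library per group leaves no spread between replicates. Where a count was 0, the fold is a lower bound against a floor of 3 counts in that library, which is 0.197 CPM in the control and 0.193 CPM in the AI662270 library. That bound takes the count of the other library as it stands, so the exact interval of such a ratio starts lower. Intervals and floors cover counting error only, since reads carried no molecular identifiers.

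For 35 gene lists the median log2 ratio of measured members was set beside those of 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes these 2 libraries and is no p-value. The range beside a median is a 95% order-statistic interval over members. The groups, lists, rule of size, alternatives and rule for named genes were fixed before the data were examined. Named genes are AI662270, the 12 highest and 12 lowest genes by the bound of the interval nearest 1, and the 8 largest changes each way among genes with at least 50 CPM, leaving out symbols of the Gm and Rik series. In each list up to 4 members past the rule with the largest log2 ratios were named, or the 2 most abundant where none passed. Ctgf, Mettl3, Sox9, Col1a1, Col3a1, Fn1, Acta2, Tgfb1 and the 3 nearest measured genes on each side of AI662270 were named whatever their values. Some genes that this rule takes are not reported here. Of a symbol held by several rows, the row with the most counts was used.

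The rule of size was tested on simulated data. Poisson counts were drawn for the AI662270 library against the control library from the real means, with 200 genes changed. Among 13264 measured genes, 96% of genes changed 3-fold, 96% of those changed 4-fold and 98% of those changed 8-fold were recovered, 0 of 50 changed 1.5-fold were called, and 3 of 13072 unchanged measured genes were called. Of the 200 changed genes, 8 lay below the CPM minimum in the simulated libraries and count as not recovered. The simulation holds no difference between cultures.

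Alternatives were scaling by total counts, by DESeq2 1.42.0 size factors and by upper quartiles, pseudocounts of 0.1 and 2 CPM, no filter or a mean of at least 5 CPM, protein-coding genes alone, thresholds of 1.5-fold and 3-fold, and the FPKM columns with a pseudocount of 0.5 FPKM. A correction for gene length and GC content in 20 bins each and a comparison against the median of each chromosome were added after the data were seen. GC content came from the longest transcript of each gene and was known for 99.1% of measured genes. Figures were drawn with matplotlib 3.10.9.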

Results

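RNA was profiled by sequencing in SV40 MES13, a mouse line that the labels describe as mesangial and immortalised with SV40 sequences. The line had been infected with a lentivirus carrying the long noncoding RNA AI662270 or with a control lentivirus, and infected cells were selected with puromycin. Each group held 1 library, so no difference below has a replicate check and each comparison describes 2 libraries, not 2 conditions. The control library held 15727023 counts over 20259 genes with at least 1 count, and the AI662270 library held 15062482 counts over 21262 genes. The 10 most abundant genes took 3.30% of the counts in the control library and 4.06% in the AI662270 library, and mt-Co1 led both. Ratios are given as the AI662270 library over the control library, with counts in the order control, AI662270. A bracketed range beside a level or a fold is a 95% exact counting interval and covers counting error only, and one beside a median is a 95% order-statistic interval over the members of the set.

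The first comparison asked whether the delivered transcript was present in the library labelled with it. AI662270 (ENSMUSG00000087107) lies on chromosome 11 from 83223576 to 83226604 on the plus strand in build mm10, where it is annotated as a processed transcript without a coding sequence. It had 0 counts in the control library, which allows up to 3 counts or 0.197 CPM (counts scaled to library size). It had 241 counts in the AI662270 library, or 15.5 CPM (13.6 to 17.5). Against a floor of 3 counts in the control library, the level was at least 78.4-fold higher in the AI662270 library, and the exact interval of the ratio starts at 63.3. No other gene with a count overlaps the locus, and reads from the viral copy and from the chromosomal copy are counted at the same place.

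The main question was which transcripts differed in the line carrying AI662270. Of 13268 measured genes, 742 were at least 2-fold higher and 759 at least 2-fold lower in the AI662270 library, and 88.7% of measured genes had a log2 ratio between -1 and 1 at the pseudocount of 0.5 CPM. The higher genes were mostly of low abundance. Among the 5152 genes with a mean of at least 50 CPM, 67 were higher and 268 lower. The number of higher genes was 400 with a pseudocount of 2 CPM and 391 when only genes with a mean of at least 5 CPM were counted.

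**Figure D1:**
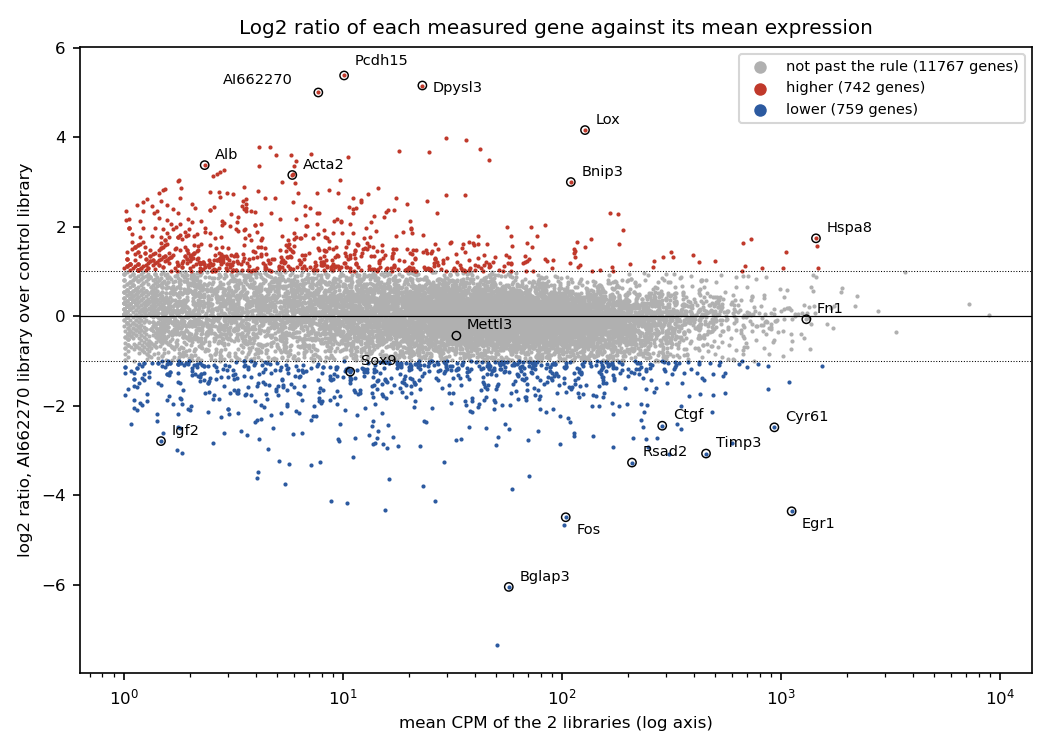
Log2 ratio of the AI662270 library over the control library (vertical axis) against the mean CPM of both libraries (horizontal log axis) for 13268 measured genes, 1 library per group. Red points mark the 742 higher genes, blue points the 759 lower genes, dotted lines a log2 ratio of 1 and -1, and circles the labelled genes. AI662270, Pcdh15, Dpysl3 and Lox stand at the top, and Bglap3, Fos and Egr1 near the bottom.

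Among the genes most clearly higher, Pcdh15, a protocadherin of sensory hair cells on chromosome 10 from 73099342 to 74649737, had 0 and 316 counts. Against the floor of 3 counts Pcdh15 was at least 103-fold higher, and its exact interval starts at 83.1. Dpysl3, a cytoskeletal regulator of growing neurites, had 12 and 707 counts and was 57.5-fold higher (32.7 to 112). Lox, which encodes the lysyl oxidase that cross-links collagen and elastin, had 199 and 3771 counts and was 18.5-fold higher (16.03 to 21.4). Pdzrn3 had 3 and 142 counts, a ratio of 46.2 (15.5 to 227). Cdh11, a cadherin of mesenchymal cells, was 29.3-fold higher (12.3 to 91.5). The plasma protein genes Alb and Gc, both on chromosome 5, had 0 and 73 counts and 62 and 1080 counts. Alb was at least 23.7-fold higher, with an exact interval from 18.8, and Gc 16.997-fold higher (13.2 to 22.3). Ak4, a mitochondrial adenylate kinase, was 18.1-fold higher (13.5 to 24.8). Dnajc6, which lies close to Ak4 on chromosome 4, had 0 and 55 counts and was at least 17.9-fold higher, with an exact interval from 14.1. Stc1, which encodes the secreted glycoprotein stanniocalcin, had 0 and 56 counts and was at least 18.2-fold higher, with an exact interval from 14.3. Among abundant genes, Bnip3, Pdk1 and Egln1 of the hypoxia list were followed by Nos2, the inducible nitric oxide synthase, which was 4.13-fold higher (3.75 to 4.57). Loxl1, a relative of Lox, was 4.05-fold higher (3.59 to 4.57). Fam162a was 4.03-fold higher (3.63 to 4.48) and overlaps Wdr5b. The metallothionein gene Mt1 was 3.80-fold higher (3.57 to 4.06).

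Among the genes most clearly lower, Bglap3, an osteocalcin-related gene on chromosome 3 from 88368616 to 88372743, had 1722 and 19 counts and was 92.9-fold lower (59.3 to 155). Bglap3 has close copies nearby, and its value is uncertain to the extent that reads are shared with them. The membrane dipeptidase gene Dpep1 was 31.5-fold lower (16.9 to 66.3). Soat2, a cholesterol acyltransferase, had 121 and 3 counts, a ratio 41.3-fold lower (13.8 to 203). The growth factor gene Igf2 had 45 and 0 counts and was at least 15.4-fold lower, and Trdc, a T cell receptor constant segment, had 56 and 0 counts and was at least 19.1-fold lower. Igf2 overlaps its antisense gene Igf2os, from which it cannot be separated without strand. Entpd4b was 16.7-fold lower (8.85 to 35.5) and is uncertain because Entpd4 is a near-identical copy. Gadd45a, a growth arrest gene, was 12.4-fold lower (10.6 to 14.7). Timp3, an inhibitor of matrix metalloproteinases that lies within Syn3, had 12369 and 1504 counts and was 8.43-fold lower (7.99 to 8.90).

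Immediate early genes, which serum and growth factors induce within minutes, were lower as a group. Of 29 measured members, 20 were lower and 0 higher, and the median log2 ratio was -1.55 (-2.19 to -0.88). Fos was 23.8-fold lower with 3039 and 131 counts, and Egr1 was 20.6-fold lower with 32451 and 1614 counts (19.6 to 21.7). Egr2 was 31.0-fold lower (11.8 to 116) and Ier2 8.53-fold lower (7.99 to 9.11). The list median lay at percentile 0 of 10000 random lists of the same size and expression. Fos lies on chromosome 12, whose 477 measured genes had a median log2 ratio of -0.35.

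Targets of YAP and SRF, transcriptional regulators that respond to cell shape and actin, were also lower. Of 18 measured members 6 were lower and 1 higher, with a median of -0.65 (-1.02 to -0.41) at percentile 0.01. Cyr61 had 24077 and 4407 counts and was 5.60-fold lower (5.42 to 5.78). Ctgf, the connective tissue growth factor gene, had 7383 and 1381 counts and was 5.48-fold lower (5.17 to 5.81), and Ankrd1 was 4.41-fold lower (4.23 to 4.59). The member that went the other way was Acta2, the smooth muscle actin gene, which had 12 and 171 counts and was 13.9-fold higher (7.76 to 27.4).

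The list for the unfolded protein and amino acid responses split. Of 32 measured members 17 were lower and 4 higher, and the median was -1.22 (-1.73 to -0.37) at percentile 0. The lower members included Atf3, 7.69-fold lower (7.17 to 8.25), the glutathione-degrading enzyme gene Chac1, 7.39-fold lower (6.62 to 8.27), and Cth, 7.07-fold lower (5.89 to 8.54). Ppp1r15a, whose product directs dephosphorylation of eIF2alpha, was 6.69-fold lower (6.26 to 7.17). The 4 higher members were Hsp90b1, Dnajc3, Manf and Sdf2l1, which encode proteins of the endoplasmic reticulum and were picked out after their values were seen. Their folds were 2.17, 2.52, 2.04 and 2.12.

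Interferon-stimulated genes were lower in 17 of 36 measured members and higher in 0. Their median was -0.93 (-1.34 to -0.62) at percentile 0. Rsad2, which encodes the antiviral enzyme viperin, had 5763 and 605 counts and was 9.76-fold lower (8.98 to 10.6). Ifi44 was 4.06-fold lower (3.77 to 4.39), Ifit3 4.04-fold lower (3.58 to 4.58) and Cmpk2 3.82-fold lower (3.37 to 4.34). Ifit3 is uncertain because Ifit3b is a close copy, and Rsad2 and Cmpk2 lie side by side on chromosome 12. Antigen presentation genes had 3 of 14 members higher and 0 lower, with a median of 0.34 (-0.13 to 1.07) at percentile 99.87. Calr, which encodes an endoplasmic reticulum chaperone, was 2.68-fold higher (2.62 to 2.75). B2m, the light chain of class I molecules, was 2.10-fold higher (2.06 to 2.14), and Psmb9, which overlaps Tap1, was 2.35-fold higher (2.09 to 2.64). The cytokine, chemokine and NF-kB list held 8 lower and 6 higher members of 30, with a median of -0.51 (-0.99 to 0.005) at percentile 0, and of -0.23 when members of any level were included. Its chemokines Ccl20 and Cxcl2 were 8.14-fold lower (6.09 to 11.1) and 6.44-fold lower (5.84 to 7.11). Vcam1, an adhesion receptor for leukocytes, was 6.67-fold higher (4.91 to 9.23), and the acute phase gene Saa3 was 5.48-fold higher (4.07 to 7.51).

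**Figure D2:**
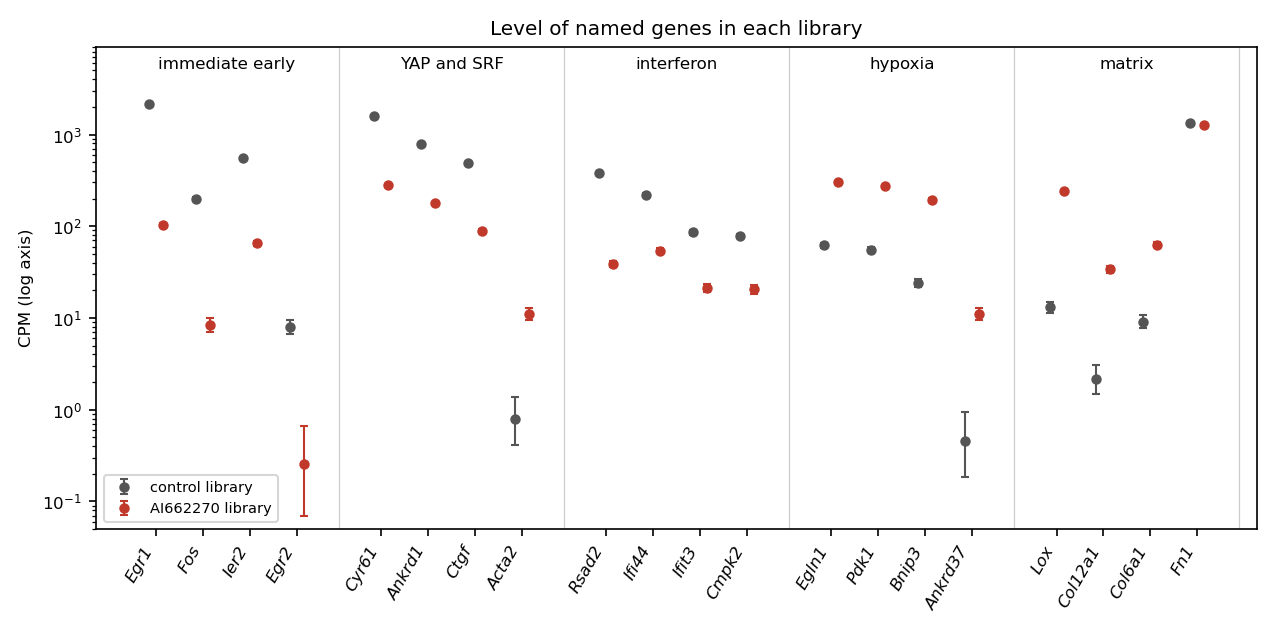
CPM (vertical log axis) of 20 genes in the control library (grey) and the AI662270 library (red), 1 library per group. Points are single libraries and bars are 95% exact Poisson intervals, which cover counting error only. Egr1 stood at 2134 CPM in the control library and 104 CPM in the AI662270 library, and Lox at 13.1 and 242 CPM.

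Genes of hypoxia and glycolysis were higher as a group. Of 31 measured members 12 were higher and 1 lower, and the median was 0.87 (0.53 to 1.29) at percentile 100. Bnip3, a mitophagy receptor, had 366 and 3049 counts and was 8.13-fold higher (7.29 to 9.08). Pdk1, the kinase that inhibits pyruvate dehydrogenase, was 4.99-fold higher (4.63 to 5.38), and Egln1, an oxygen-sensing prolyl hydroxylase, was 4.86-fold higher (4.53 to 5.22). Ankrd37 had 7 and 173 counts and was 24.1-fold higher (11.5 to 60.9), although it overlaps Ufsp2 and Lrp2bp. The lower member was Car12, a carbonic anhydrase, which was 2.51-fold lower (1.85 to 3.45). It is named because it alone passed the size rule in that direction. Other members had log2 ratios below 0 that did not pass it. Heat shock genes had 4 of 14 members higher and 0 lower, with a median of 0.69 (0.13 to 1.74) at percentile 100. Hspa8 had 10123 and 34662 counts and was 3.34-fold higher (3.27 to 3.42), and Hsph1 was 2.52-fold higher (2.41 to 2.64). Hspa1a and Hspa1b were 3.97-fold and 3.47-fold higher and are uncertain because the pair is nearly identical. Housekeeping genes, used as internal standards, had 4 of 16 members higher and 0 lower, with a median of 0.35 (-0.12 to 1.07) at percentile 99.97. Tfrc, the transferrin receptor gene, was 2.72-fold higher (2.60 to 2.85), and B2m is a member of this list as well. Ppia was 2.12-fold higher (2.07 to 2.17). Gapdh had 111 and 357 counts, a low level for this gene. Gapdh and Ppia have many processed pseudogenes, so their values are uncertain.

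Other metabolic lists had medians nearer to 0. Fatty acid metabolism held 4 higher and 1 lower of 25 members, with a median of 0.27 (-0.07 to 0.43) at percentile 99.87. Angptl4, an inhibitor of lipoprotein lipase, was 6.33-fold higher (5.12 to 7.90), Fabp5 was 2.32-fold higher (1.99 to 2.71), and the nuclear receptor genes Pparg and Ppara had 9 and 48 counts and 5 and 31 counts. Ppara no longer passed the size rule with a pseudocount of 2 CPM or on FPKM, nor Pparg with that pseudocount. The NRF2 and glutathione list held 2 higher and 3 lower of 25, with a median of 0.22 (-0.14 to 0.49) at percentile 99.4. Sod3 was 12.4-fold higher (6.87 to 24.4), while the cystine transporter gene Slc7a11 was 5.88-fold lower (5.15 to 6.74) and Osgin1 2.80-fold lower (2.48 to 3.17). No member passed the size rule among 23 cholesterol synthesis genes (median 0.07, percentile 91.2), 28 nuclear-encoded respiratory chain genes (median 0.08, percentile 95.3), 12 mitochondrially encoded proteins (median 0.14, percentile 88.5) or 35 cytosolic ribosomal proteins (median 0.05, percentile 92.3). The most abundant members of these lists had log2 ratios of -0.34 for Srebf2, -0.41 for Cyp51, -0.19 for Atp5b, 0.23 for Atp5a1, 0.03 for mt-Co1, 0.12 for mt-Nd1, 0.45 for Rplp0 and 0.24 for Rps2.

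Extracellular matrix accumulates in the mesangium in chronic kidney disease, and 4 of 21 measured matrix genes were higher and 0 lower. The median was 0.13 (-0.18 to 0.79) at percentile 92.2. Col12a1 was 15.6-fold higher (10.98 to 22.9), Col6a1 6.87-fold higher (5.75 to 8.27), Col6a2 7.62-fold higher (5.59 to 10.6) and Fbn1, the fibrillin gene, 2.19-fold higher (1.63 to 2.98). Fbn1 no longer passed the size rule with a pseudocount of 2 CPM or on FPKM. Fn1, the fibronectin gene, had 20327 and 19862 counts and a log2 ratio of -0.07. Col1a1 had 67 and 124 counts and a log2 ratio of 0.79, and Col3a1 had 0 counts in both libraries. Matrix remodelling genes went both ways, with 5 higher and 5 lower of 27 and a median of 0.37 (-0.56 to 0.84) at percentile 99.99. Lox and P4ha3, a collagen prolyl hydroxylase gene with 1 and 45 counts, were among the higher members. Timp3 and Plau, the urokinase gene, were among the lower ones, and Plau was 4.26-fold lower (3.88 to 4.69).

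TGF-beta signalling genes and targets held 5 higher and 3 lower of 27 measured members, with a median of -0.05 (-0.73 to 0.27) at percentile 52.9. Thbs1, which encodes a glycoprotein that activates latent TGF-beta, was 7.71-fold lower (7.08 to 8.40), Ctgf was lower as given for the YAP and SRF targets, and Inhba was 3.99-fold lower (3.48 to 4.59). Ltbp2, a latent TGF-beta binding protein gene on chromosome 12, was 6.83-fold higher (5.29 to 8.94). Tgfb1 itself had 774 and 958 counts and a log2 ratio of 0.27. The myofibroblast and contractile list held 2 higher and 2 lower of 13, with a median of -0.22 (-0.72 to 0.93) at percentile 15.96, and of 0.12 when members of any level were included. Besides Acta2, the intermediate filament gene Vim was 2.58-fold higher (2.48 to 2.68). Cald1 and Smtn, both contractile apparatus genes, were 2.20-fold lower (2.14 to 2.27) and 2.13-fold lower (2.004 to 2.26), and Smtn lost its place past the rule when libraries were scaled by total counts. Regulators of epithelial-mesenchymal transition held 3 higher and 3 lower of 15, with a median of 0.33 (-0.93 to 0.74) at percentile 98.8. The transcription factor gene Snai2 had 0 and 40 counts and was at least 13.01-fold higher, with an exact interval from 10.1. Runx1 was 2.41-fold lower (2.17 to 2.67). The median of this list was -0.069 when only members with a mean of at least 5 CPM were kept.

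The growth factor list also holds receptors, binding proteins and genes of the angiotensin and endothelin axes. Of its 21 measured members 5 were lower and 3 higher, with a median of -0.21 (-0.89 to 0.49) at percentile 6.78. The median was 0.34 when members of any level were included. The EGF receptor ligand genes Areg and Hbegf were 8.28-fold lower (6.33 to 11.02) and 5.21-fold lower (4.75 to 5.72), and Fgf7 was 5.58-fold higher (4.35 to 7.24). The Wnt and Notch list held 4 higher and 3 lower of 26, with a median of 0.10 (-0.47 to 0.61) at percentile 77.6. Rspo3, a Wnt agonist gene, was 17.2-fold higher (9.12 to 36.4), Wnt5a 8.71-fold higher (5.84 to 13.5), Hey1 7.22-fold higher (2.83 to 23.5) and Notch3 4.06-fold higher (3.33 to 4.99). Hey1 no longer passed the size rule with a pseudocount of 2 CPM.

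Cell cycle lists showed few members past the size rule. Among 30 genes of the G1/S step and DNA replication 0 passed, with a median of -0.0029 (-0.18 to 0.10) at percentile 78.02, and Mcm7 and Rrm1 had log2 ratios of 0.16 and 0.34. Among 32 genes of G2/M and mitosis 1 was higher, with a median of 0.14 (-0.03 to 0.30) at percentile 99.7. It was Ccnf, which encodes cyclin F and was 2.96-fold higher (2.69 to 3.26). Targets of p53 held 4 higher and 5 lower of 24, with a median of -0.05 (-0.70 to 0.42) at percentile 49.6. The death receptor gene Fas was 8.62-fold higher (5.64 to 13.8), whereas Plk2 was 7.10-fold lower (6.80 to 7.42) and Gdf15 5.77-fold lower (5.48 to 6.09).

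RNA methylation genes, whose products write, erase and read N6-methyladenosine, held 0 members past the rule of 23 measured, with a median of -0.02 (-0.20 to 0.06) at percentile 70.1. Mettl3, the catalytic writer, had 578 and 436 counts and a log2 ratio of -0.44, and it overlaps Tox4. Eif3a and Hnrnpa2b1, the most abundant members, had log2 ratios of -0.58 and 0.42. The labels name a pair of genes, AI662270 and Sox9, and their protocol gives Sox9 as the transcript followed by quantitative PCR. The same protocol names the cell line in place of the transcript that the virus carries, so its mention of Sox9 is uncertain. Sox9 had 234 and 97 counts and was 2.47-fold lower (1.94 to 3.17). With AI662270 at its bound, the median of this pair of opposite changes was 2.53, and at the pseudocount it was 1.88 at percentile 99.3. Since AI662270 is the delivered transcript, a high value for the pair was set by the design. This median and percentile therefore carry no result about a list. A mixed list of long noncoding RNAs, with nuclear, imprinted and small RNA host transcripts among them, held 3 lower and 0 higher of 13 measured members. Its median was -0.79 (-1.36 to 0.28) at percentile 0. The 3 lower members are host genes of small RNAs. Snhg12 was 3.42-fold lower (2.83 to 4.14), Mir17hg 2.71-fold lower (2.10 to 3.52) and Snhg1 2.61-fold lower (2.43 to 2.81).

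**Figure D3:**
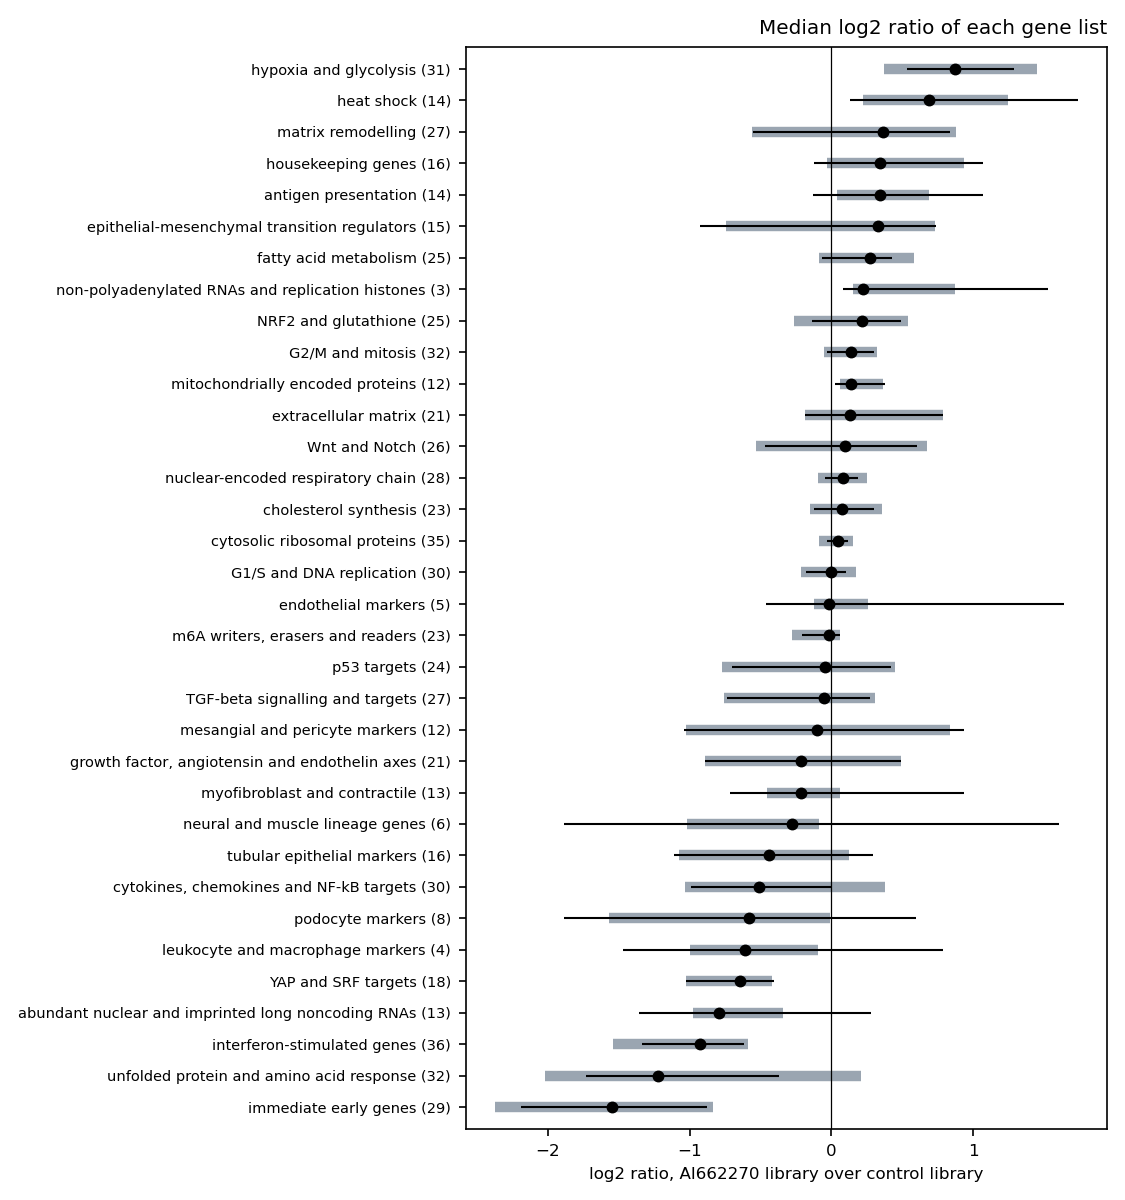
Median log2 ratio of the AI662270 library over the control library (horizontal axis) for each gene list with at least 3 measured members, with the number of measured members in brackets. Points are medians, thin black lines the 95% order-statistic interval of the median over members, and grey bars the range between quartiles. Immediate early genes lie lowest at -1.55, and hypoxia and glycolysis genes highest at 0.87.

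Markers of cell types were read to describe what the line expressed. The mesangial and pericyte list held 12 measured markers of 26, with 2 higher, 4 lower and a median of -0.10 (-1.04 to 0.93) at percentile 23.2, and of 0.25 when members of any level were included. Sept4 was 5.30-fold lower (4.34 to 6.52) and Gata3 3.12-fold lower (1.96 to 5.11), while Anpep had 8 and 39 counts. Gata3 and Anpep no longer passed the size rule with a pseudocount of 2 CPM or on FPKM. The tubular epithelial list held 16 measured markers of 25, with 5 lower and 1 higher and a median of -0.44 (-1.11 to 0.29) at percentile 0.53. Krt18 had 11914 and 5085 counts and was 2.40-fold lower (2.32 to 2.48). Cldn4, a tight junction gene, was 6.75-fold lower (4.03 to 12.001), Aqp1 3.72-fold lower (2.81 to 4.98) and the injury marker Havcr1 2.70-fold higher (1.52 to 5.01). Havcr1 no longer passed the size rule with a pseudocount of 2 CPM or on FPKM. The tubular median was 0.0586 when members of any level were included. Podocyte markers held 3 lower and 0 higher of 8, with a median of -0.58 (-1.89 to 0.60) at percentile 0.56, of -0.34 when members of any level were included and of -0.19 on FPKM. Clic5 was 3.79-fold lower (3.29 to 4.37) and Podxl 2.90-fold lower (2.65 to 3.17). Endothelial markers had 5 measured members with a median of -0.01 at percentile 39.95, of which Flt4 was 3.29-fold higher (2.60 to 4.21). Leukocyte and macrophage markers had 4 measured members with a median of -0.61 at percentile 3.27, and of -0.16 when members of any level were included. Of the 4, Csf1r was 2.86-fold lower (2.37 to 3.47) and overlaps Hmgxb3. Neural and muscle lineage genes had 6 measured members with a median of -0.28 at percentile 11.1, and of -0.14 when members of any level were included. Tubb3 was 3.09-fold higher (2.73 to 3.50), Tnnt2 4.12-fold lower (2.9999 to 5.76) and Pax6 3.95-fold lower (1.68 to 10.8). Pax6 no longer passed the size rule with a pseudocount of 2 CPM or on FPKM. Replication histones and RNAs without a poly(A) tail had 3 measured members of 18 and a median of 0.22 at percentile 62.1. Of these the histone gene Hist1h2bc was 3.13-fold higher (2.32 to 4.30).

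The genes next to AI662270 were read to describe the locus. None of the 5 neighbouring genes given here passed the size rule. On the left lay the schlafen genes Slfn2, 153 kb away with 47 and 28 counts, Slfn10-ps with 48 and 26 counts, and Slfn8 with 26 and 30 counts. Schlafen genes form a family of close copies, so these low values are uncertain. On the right lay Ap2b1, 72.4 kb away with 5970 and 6052 counts, and 1700020L24Rik with 20 and 14 counts. Their log2 ratios were -0.02 for Ap2b1, -0.38 for 1700020L24Rik, -0.64 for Slfn2, -0.75 for Slfn10-ps and 0.13 for Slfn8.

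Gene classes were compared to see which kinds of transcript differed. Protein-coding genes took 97.9% of the counts in the control library and 98.0% in the AI662270 library, and 658 of 11858 measured ones were higher and 619 lower. Of 188 long intergenic noncoding RNAs 12 were higher and 22 lower, although their median log2 ratio was 0.11. Of 509 processed pseudogenes 18 were higher and 14 lower. Of 159 antisense genes 13 were higher and 6 lower, and of 31 bidirectional promoter noncoding RNAs 3 were higher and 1 lower. Processed transcripts, the class of AI662270, had 17 higher and 16 lower of 126. Of 134 genes of the annotation class TEC, which still need experimental evidence, 7 were higher and 23 lower, and of 33 unprocessed pseudogenes 0 were higher and 5 lower. Of 106 unannotated loci that the authors added to the annotation, 8 were higher and 42 lower. All loci added by the authors, measured or not, took 0.270% of the counts in the control library and 0.136% in the AI662270 library. The median log2 ratio of the 106 measured ones was -0.65.

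The authors' deposited table gave a test of the reads of 1 library against 1 library, which compares those libraries and not the conditions. The test in the authors' deposited table covered 20667 genes and listed 897 at an adjusted p-value under 0.05, of which 457 were higher and 440 lower. Of these 897 listed genes in the authors' deposited table, 760 also passed the size rule in the same direction, and 0 passed it in the other. The remaining 137 lay below the CPM minimum. The size rule passed 741 genes that the authors' deposited table did not list, 377 higher and 364 lower.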

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

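No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. The length and GC correction and the comparison within chromosomes were chosen after the data were seen. Scaling by total counts, upper quartiles or DESeq2 size factors moved the median of all genes by 0.10, 0.07 and 0.03 on the log2 scale, and gave 870, 820 and 778 higher and 615, 655 and 707 lower genes. The number of higher genes moved from 742 to 400 with a pseudocount of 2 CPM, to 391 with a mean of at least 5 CPM and to 487 with FPKM. The main 742 include all 400 and all 391 of those genes. The cause was not tested beyond the construction of these settings, which weigh against low values. Thresholds of 1.5-fold and 3-fold gave 1705 and 247 higher and 1893 and 262 lower genes. The length and GC correction gave 740 higher and 740 lower genes, and ratios set against the median of each chromosome gave 716 and 735. AI662270 had no counts in the control library, so its log2 ratio of 5.00 depends on the pseudocount, with 7.28 at 0.1 CPM, 3.13 at 2 CPM and 3.50 on FPKM. Its fold against the floor was 78.4, and 80.3 to 83.9 with the other scalings. Of 349 list medians under alternatives 2 left their interval and 25 changed sign, 3 of them in lists beyond the central 95% of random lists. The median of the genes named in the labels turned to -1.24 with protein-coding genes alone, which leaves Sox9. The epithelial-mesenchymal transition median turned to -0.069 with a mean of at least 5 CPM and the tubular median to 0.0586 without a filter, where the settings change which members count. Without a filter the medians of the growth factor list turned to 0.34, of the mesangial and pericyte list to 0.25, of the myofibroblast list to 0.12 and of the endothelial list to 0.17, while those of the cytokine, podocyte, leukocyte and neural lists came nearer to 0, at -0.23, -0.34, -0.16 and -0.14. Scaling by total counts moved the RNA methylation median from -0.02 to 0.081 and the ribosomal protein median from 0.05 to 0.14, by the same 0.10 as the median of all genes. Medians near 0 of the TGF-beta, p53, G1/S, endothelial and RNA methylation lists changed sign with the scaling, so no direction is given for them. None of the named genes past the rule changed sign. Of 111 named genes past the rule, 110 stayed past it with total counts, 111 with each other scaling and with a pseudocount of 0.1 CPM, 103 with a pseudocount of 2 CPM and 105 on FPKM. Smtn was lost with total counts. Anpep, Fbn1, Gata3, Havcr1, Pax6 and Ppara were lost with a pseudocount of 2 CPM and on FPKM, and Hey1 and Pparg with that pseudocount alone. Of the 897 genes in the authors' deposited table, 760 also passed the rule of size. Depth limits genes near 1 CPM, where 3 counts stand for 0.197 CPM in the control library.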

Other observations

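Of the tests in this part, the 2 on gene length and GC content were set before their results were seen, and the others only after. The lists and genes described next were also chosen after their values were seen. Among the unannotated loci added by the authors, 43 measured ones carry a match to a retroviral protein in the deposited description, and 25 of them were lower and 2 higher in the AI662270 library. Their summed level was 2206 CPM in the control library and 1035 CPM in the AI662270 library, and their median log2 ratio was -1.66. A Gag-Pol locus on chromosome 5 from 92543037 to 92551786 had 2991 and 113 counts and was 27.1-fold lower (22.5 to 33.0). Of 6 measured loci with a match to a LINE-1 protein 3 were lower and 0 higher, with a median log2 ratio of -1.07. The lowest, on chromosome 2 from 43256516 to 43264461, had 1544 and 2 counts, a ratio 791-fold lower (219 to 6539), while one on chromosome X had 187 and 312 counts and a log2 ratio of 0.68. The retroviral loci did not all share the pattern, since an envelope locus on chromosome 17 from 34996782 to 35000827 had 7073 and 7831 counts. Reads of repeated elements are shared between copies, so single loci are uncertain.

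A list of mesenchymal genes had 6 of 14 measured members higher and 0 lower, with a median log2 ratio of 0.84 (0.54 to 2.74). A list of epithelial genes had 8 of 18 lower and 0 higher, with a median of -0.87 (-1.26 to -0.38). Both were put together after the values were seen, so their shift is no independent support. Related lists fixed beforehand had medians of -0.22 (-0.72 to 0.93) for myofibroblast genes and -0.10 (-1.04 to 0.93) for mesangial markers. Tubular markers had -0.44 (-1.11 to 0.29), and epithelial-mesenchymal transition regulators 0.33 (-0.93 to 0.74). Both libraries of this line, which the labels describe as mesangial, held epithelial transcripts of the kidney, and whether the cells are mesangial was not tested here. Pax8 had 2812 and 1803 counts and Cdh16 had 4945 and 4409 counts. The mesangial marker Itga8 had 0 counts in both libraries, Des had 26 and 58 counts and Pdgfrb had 185 and 338 counts. Pax8, Cdh16, Itga8, Des and Pdgfrb were picked from longer lists. Of the tubular list 16 of 25 members were measured, and of the mesangial and pericyte list 12 of 26. Of the collagen genes Col1a1, Col1a2 and Col3a1, 1 was measured. The class II antigen presentation genes H2-Ab1, Cd74 and H2-Eb1 were 7.23-fold higher (5.21 to 10.3), 2.30-fold higher (1.70 to 3.16) and 8.05-fold higher (2.86 to 31.3), while interferon-stimulated genes were lower.

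The lists of immediate early genes, of YAP and SRF targets, of the unfolded protein and amino acid responses and of interferon-stimulated genes had medians below 0. The third of these split, with 17 lower and 4 higher of 32 members. Subtracting the median of genes of like length and then of like GC content left the list median nearest to 0, that of YAP and SRF targets, at -0.64, which argues against such a bias as the whole cause. Loss of short-lived transcripts in 1 culture would lower other short-lived transcripts too. A list of 30 outside these groups had 6 lower and 2 higher members, a median of 0.022 (-0.57 to 0.23) and a lower quartile of -0.89, against a median of -1.55 for the immediate early genes. Its members went both ways and its lower quartile lies below the upper quartile of the immediate early genes, -0.83, so such a loss stays open. Slower proliferation would lower both cell cycle lists, and the lower of their medians was -0.0029 (-0.18 to 0.10) for G1/S genes. These lists give no sign of it. Growth itself was not measured, so slower proliferation is not excluded in this line immortalised with SV40 sequences. Other differences in handling, density or serum at harvest and an effect of AI662270 both remain open and may each contribute, since each group is 1 culture.

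Hypoxia and glycolysis genes were higher together. After the length and GC correction their median was 0.82, against 0.87 before, so this bias is not the whole cause. A difference in density, medium or oxygen between the cultures would raise this list, and its median of 0.87 cannot be told apart from an effect of AI662270 because each group is 1 culture. Within the list Hk2 and Pfkfb3 had log2 ratios of -0.80 and -0.80, and Vegfa had -0.36.

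Genes of chromosome 12 were lower as a set, with a median log2 ratio of -0.35 (-0.43 to -0.31) over 477 genes, or 78.3% of the control level. The medians of 19 other nuclear chromosomes, the remaining autosomes and X, lay between -0.14 and 0.13. Chromosome Y is not among them. A few strongly lower genes would leave the rest in place, but 73.8% of chromosome 12 genes (69.6 to 77.7, exact binomial) lay below the median of all measured genes. That interval takes the genes as independent and covers no spread between cultures. The chromosome was picked because its median was the most extreme, so a majority of its genes below the overall median followed from that choice. The share is therefore no separate support. The 404 chromosome 12 genes not past the size rule had a median of -0.31, so the shift did not rest on the strongly lower genes. Fewer copies of the chromosome in the AI662270 subline stay open, since copy number was not measured. Of the 10 windows of 10 Mb with 20 or more genes, 8 (80%) had a median below -0.15, which restates the lower median of the set and decides nothing. The window from 30000001 to 40000000 had a median of 0.00, so a loss of part of the chromosome, or in part of the cells, is also open.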
